A study of Caenorhabditis elegans with 2 samples.

How the data were processed

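FKH-6-GFP was measured by ChIP-seq in 2 biological replicates of whole late embryos, which form 1 group. Per the labels, the antibody was against GFP, chromatin was sheared by sonication, and a control experiment exists; control libraries were not analysed here. The 8 peak lists give regions for each replicate, for both replicates pooled, and for the reproducible set, in each of 2 genome builds, ce10 and ce11. The authors called regions per replicate and on the pooled replicates, and the reproducible list is their pooled list thresholded by the irreproducible discovery rate, per the deposited descriptions of the lists. The peak caller, aligner, their versions and the threshold are not given in the sources used here.

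The deposited signal of a region, in column 7, is the authors' value on a scale that is not given in the sources used here, and it was used only to rank and filter regions within a list. The deposited −log10 q-value, in column 9, is also the authors', and was used for a stricter alternative. The lists hold no read counts, so the depth per sample and its effect on the number of regions are unknown. Intervals on shares are 95% Wilson intervals and cover counting error only; a count of 0 was given the limit of 3 counts. There were 0 columns of other samples.

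The values were computed with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, with figures by Matplotlib 3.10.9. The genome was WBcel235, which is ce11, with the gene annotation of Ensembl release 115. Chromosome positions were not converted between builds, and all annotation work used ce11. A gene start is the 5' end of the annotated gene. Nuclear tests left out the mitochondrial regions. Regions matched between lists when summits were within 100 bp. Background sets were 1000 random circular shifts of the regions within their chromosomes and the pooled regions outside the reproducible list. The pooled list is permissive: per the deposited descriptions it holds peaks and background for the reproducibility step, its lowest −log10 q-value is 0.0178, and 1098 of its 26164 regions reach 2. Most of the comparison regions are therefore weak or background, and odds ratios against them also reflect signal strength. The 340 other nuclear regions at a −log10 q-value of 2 or more served as a stricter background, chosen after the data were seen. Neighbouring regions and genes that share a promoter are not independent, so p-values of the Fisher's exact and McNemar tests are likely too small. The p-values describe regions of these libraries and not a comparison of conditions.

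Gene starts within 500 bp, motifs within 50 bp of a summit against windows 300 bp to the lower-coordinate side, gene assignment within 2000 bp, non-coding starts within 500 bp and loci within 20 kb were fixed before the data were examined, as were 26 gene lists and 7 motifs. Multiple tests were adjusted by Benjamini-Hochberg at 0.05. Genes were named by a fixed rule: fkh-6 and unc-119, genes at the 15 highest-signal regions, the 4 members with the highest-signal regions of each list past the threshold, and at most 2 of each other list. A non-coding gene was named where its start was nearer than any protein-coding start and within 500 bp. Genes outside this rule (ntl-2, mlt-7, nas-30 and M01F1.9) were chosen after their values were seen.

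The procedures were tested on simulated data of 750 regions, with 20 sets each with and without a planted effect. With 150 regions moved to gene starts, 20 of 20 sets were called and 0 of 20 sets without. With a forkhead motif written into 150 summit windows, 20 sets were called, and 1 without, by the unadjusted McNemar test against the flank. Those simulated summits were placed without regard to GC content, which in the data was 50.3% at summits and 36.7% in flanks. The simulation therefore does not show that the flank comparison could find the motif in the data. With 10 muscle genes given a region, the list was called in 20 sets, and 1 list was called over all sets without. Those regions were placed at the gene starts, and in the data 5 muscle genes had a region. The power of the list test at the number found is therefore not shown. Of 500 planted matches between a list and a replicate, 500 were recovered. Motif shares were also set against 200 dinucleotide-preserving shuffles of the windows and, in bins of 5 points of GC content, against other positions. Alternatives tried were other distances, windows, flanks, stricter lists, the ce10 lists, another gene background and each replicate alone.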

Results

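The data were region lists from chromatin immunoprecipitation with sequencing (ChIP-seq) of FKH-6 in Caenorhabditis elegans. FKH-6 is a forkhead transcription factor required for development of the somatic gonad. The worms carried a transgene that expresses FKH-6 with a C-terminal GFP-FLAG tag, and chromatin was recovered with an antibody against GFP from whole hermaphrodite late embryos, 5.5 hours after synchronization by egg bleaching. There was 1 group with 2 biological replicates, so the comparisons are between replicates and between the regions and the rest of the genome. The lists hold no read counts, and the sequencing depth behind each region is unknown. Positions are in ce11 unless ce10 is named.

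The authors' reproducible list held 767 FKH-6-GFP regions, 746 on the nuclear chromosomes and 21 on the mitochondrial genome. The list made from both replicates together held 26164 regions, and the reproducible regions were the 767 with the highest signal in it, or 2.93%. Replicate 1 alone gave 19624 regions and replicate 2 alone gave 26209. At a −log10 q-value of 2 or more, replicate 1 had 0 regions (highest value 1.86) and replicate 2 had 1074. On ce10, replicate 1 had 365 such regions. The signal is the authors' value for each region and served only to rank regions within a list. The lowest signal in the reproducible list was 89.1 and the highest was 1722.

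The 15 highest-signal regions comprised 12 mitochondrial and 3 nuclear regions. The first nuclear region, ranked 5, lay in an intergenic stretch of chromosome III, 8043780 to 8044164, with its summit 530 bp upstream of K12H4.5 and a signal of 874. The regions ranked 9 and 11 lay on chromosome V at small nucleolar RNA (snoRNA) genes. The summit of the first was 23 bp from the start of C51F7.4, in the interval 12303438 to 12303809, with a signal of 712. The summit of the second was 30 bp from the start of ZK994.7, in the interval 8500386 to 8500736, within an intron, with a signal of 625. Replicate 1 ranked these 3 nuclear regions 6, 8 and 12, and replicate 2 ranked them 6, 9 and 12.

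Whether the replicates found the same places was asked by looking for each reproducible region among the 767 highest-signal regions of each replicate, with summits within 100 bp. Replicate 1 held 565 of them, or 73.7% (95% Wilson interval 70.4 to 76.7), and replicate 2 held 607, or 79.1% (76.1 to 81.9). Both replicates held 438, and 33 were in neither set. Randomly shifted nuclear regions were found in 0.158% and 0.159% of cases (permutation test, two-sided, p = 0.001, the smallest that 1000 shifts can give). With the full lists, the shares were 96.2% and 98.04%. The reproducible list was chosen from these replicates, so its recovery is not independent evidence. Across the 714 reproducible regions matched between replicates, the signals had a Spearman rho of 0.560, and across 5869 matched regions outside the reproducible list rho was 0.271. These values are across regions, which are not independent replicates.

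FKH-6-GFP regions were concentrated just upstream of protein-coding genes. Of the 746 nuclear regions, 322 had their summit within 500 bp of a protein-coding gene start, or 43.2% (95% Wilson interval 39.7 to 46.7). The share was 23.3% among the 25395 other nuclear regions of the pooled list and 18.2% in random shifts. The odds ratio against the other pooled regions was 2.5 (Fisher's exact test, two-sided, p = 8.56e-32), and the shift test gave p = 0.001, the smallest that 1000 shifts can give. The summit was upstream of the nearest start in 65.5% of reproducible regions and in 43.6% of the others. Most of the other pooled regions are weak. Among the 340 of them with a −log10 q-value of 2 or more, a background chosen after the data were seen, 36.8% were near a start, and the difference from 43.2% did not pass the test (Fisher's exact test, two-sided, p = 0.0538). Annotated starts of C. elegans genes are often trans-splice sites, so distances to transcription initiation are not known from them.

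**Figure D1:**
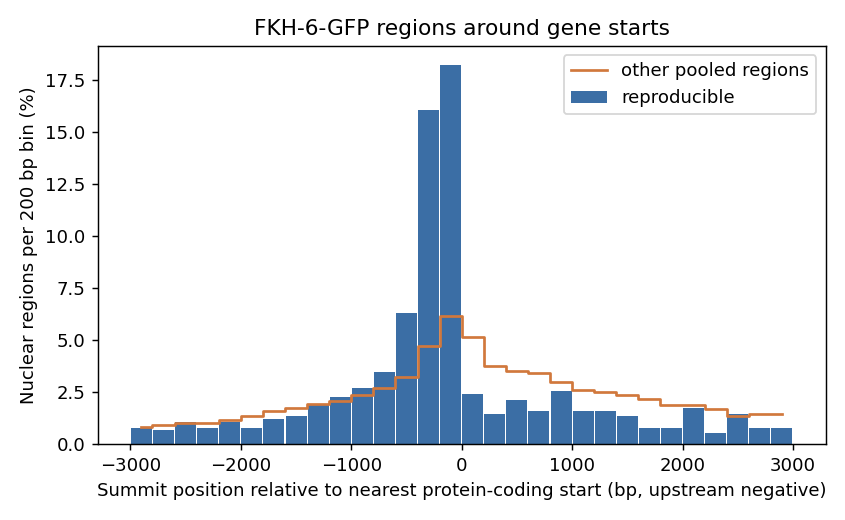
Position of summits relative to the nearest protein-coding gene start (x axis, bp, upstream negative) against the percent of nuclear regions per 200 bp bin (y axis). Bars are the 746 reproducible regions and the line is the 25395 other pooled regions; the reproducible regions pile up just upstream of the start.

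Coding sequence held few reproducible regions. Summits lay in coding exons in 24 regions, or 3.22%, against 24.3% in random shifts and 27.8% of the other pooled regions (odds ratio 0.0862, Fisher's exact test, two-sided, adjusted p = 6.74e-69). Intergenic sequence held 52.01% against 33.2% of the other pooled regions, exons of non-coding genes held 23.3% against 4.80%, and introns held 17.96% against 27.9%. The 3' UTR held 0.938% against 3.82%. For the 5' UTR the shares were 2.55% and 2.41%, with an adjusted exact p of 0.808, and random shifts gave 1.43% (adjusted permutation p = 0.0150). Adjustment was by Benjamini-Hochberg over 6 classes.

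Genes for small structured RNAs were the most over-represented neighbours of FKH-6-GFP regions. A tRNA gene start lay within 500 bp of 145 nuclear summits, or 19.4% (95% Wilson interval 16.8 to 22.4), against 1.19% of the other pooled regions and 0.591% in random shifts (odds ratio 20.05, Fisher's exact test, two-sided, adjusted p = 3.67e-112). A snoRNA start lay near 57 summits, or 7.64%, against 0.614% (odds ratio 13.4, adjusted exact p = 1.95e-38). A snRNA start, of the kind that makes spliceosomal RNA, lay near 12 summits, or 1.61%, against 0.201% (odds ratio 8.12, adjusted exact p = 4.70e-07). The annotation's class of other ncRNA genes lay near 30.6% against 11.01% (odds ratio 3.56, adjusted exact p = 7.54e-45). The miRNA starts lay near 1.07% against 0.484% (adjusted exact p = 0.0688), and random shifts gave 0.234% (adjusted permutation p = 0.00333). The shares for lincRNA (0.402% against 0.264%, adjusted exact p = 0.505), antisense RNA (0.268% against 0.0551%, adjusted exact p = 0.125), piRNA (1.61% against 2.16%, adjusted exact p = 0.461) and pseudogenes (0.804% against 1.28%, adjusted exact p = 0.454) did not pass the test. For piRNA, random shifts gave 3.87%, above the observed share (adjusted permutation p = 0.00333). Against the 340 stronger other regions, the tRNA share (6.47% there, exact p = 7.05e-09), the snoRNA share (2.35%, exact p = 0.000462) and the ncRNA share (23.8%, exact p = 0.0245) still differed, and the snRNA share (0.294%, exact p = 0.0745) did not. An rRNA start lay near 0 of 746 summits, which allows a share of up to 0.402%. Adjustment, where named, was over 10 classes. Whether these neighbours are particular to FKH-6 was not tested, since no control libraries or other factors were analysed.

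**Figure D2:**
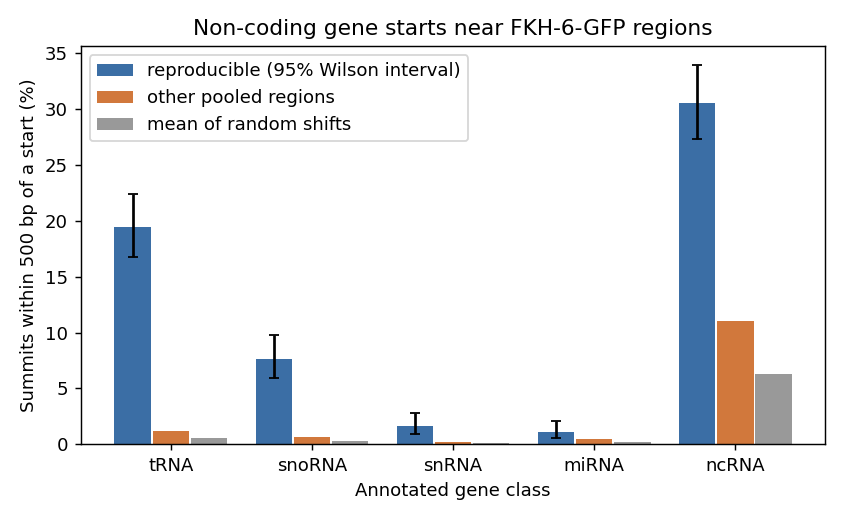
Percent of nuclear summits within 500 bp of an annotated start (y axis) for 5 gene classes (x axis). Bars are the 746 reproducible regions with 95% Wilson intervals, the 25395 other pooled regions, and the mean of 1000 random shifts; tRNA reaches 19.4% against 1.19% and 0.591%.

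The forkhead motif RYAAAYA was no more common at FKH-6-GFP summits than in the windows beside them. It was more common than at equal GC content or in shuffles of the same windows. It lay within 50 bp of 103 of 746 summits, or 13.8% (95% Wilson interval 11.5 to 16.5), and in 16.6% of the windows 300 bp away (exact McNemar test, two-sided, p = 0.143, adjusted p = 0.201). In the other pooled regions the share at the summit was 14.5% (odds ratio 0.947, Fisher's exact test, two-sided, p = 0.672, adjusted p = 0.941). These comparisons are unequal in composition, since the mean GC content was 50.3% in the summit windows and 36.7% in the flank windows and the motif is rich in A and T. In 200 dinucleotide shuffles of the summit windows the motif was in 9.03% (central 95% 7.10 to 11.1) and 0 of them reached 13.8%, while the 16.6% of the flanks lay inside the range of their own shuffles (15.1 to 19.8). Weighted to the GC content of the summits, the other pooled regions had 9.10% (permutation within GC bins, two-sided, adjusted p = 0.00699) and random nuclear positions 7.56% (adjusted permutation p = 0.00466). The shuffles and the comparisons at equal GC were chosen after the first results were seen. The stricter form GTAAACA was present at 1.07% of summits and in 0.670% of flanks (adjusted p = 0.678, exact McNemar test), inside the range of the shuffles (0.268 to 1.61). Other fixed motifs did differ from the flank. GAGAGA was at 21.4% of summits and in 6.97% of flanks (adjusted exact p = 1.18e-15), and GGGCGG at 9.38% and 1.74% (adjusted exact p = 1.24e-10). The GATA motif WGATAR was less common at summits, at 10.6% against 18.5% (adjusted exact p = 4.01e-05), but its share lay inside the range of 200 dinucleotide shuffles of the summit windows (mean 11.8%, central 95% 9.52 to 14.1). GAGAGA and GGGCGG lay above all 200 shuffles, with means of 9.65% and 5.04%. CAGCTG (3.22% against 1.47%, adjusted exact p = 0.0717) and TGASTCA (0.804% against 0.536%, adjusted exact p = 0.754) did not pass the test. Adjustment was over 7 motifs.

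**Figure D3:**
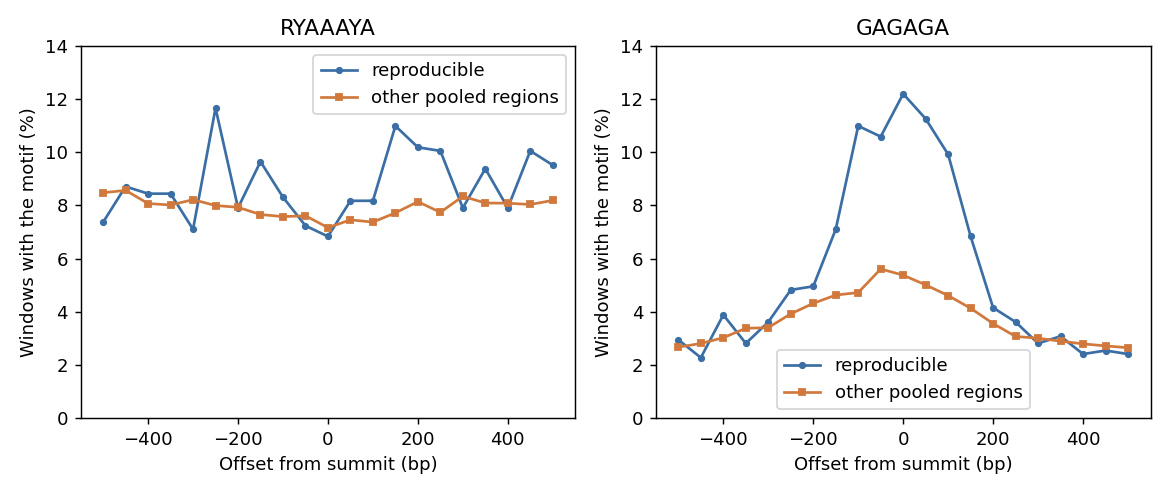
Percent of windows that hold the forkhead motif RYAAAYA or GAGAGA (y axes) by offset from the summit in bp (x axes), for reproducible and other pooled nuclear regions. GAGAGA peaks at the summit of reproducible regions, at 12.2% per window, and RYAAAYA, at 6.84% there, has no peak.

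Chromosome X carried more FKH-6-GFP regions than its length predicts. X held 180 nuclear regions, or 24.1% (95% Wilson interval 21.2 to 27.3), with 17.7% of the nuclear genome (exact binomial test, two-sided, adjusted p = 2.82e-05), and 16.9% of the other pooled regions were on X (odds ratio 1.56, Fisher's exact test, two-sided, adjusted p = 5.81e-06). Chromosomes V (13.7% of regions for 20.9% of the length, adjusted exact p = 3.10e-06) and IV (13.4% for 17.4%, adjusted exact p = 0.00642) held fewer than by length, and III held more (16.6% for 13.7%, adjusted exact p = 0.0381); none of these 3 differed from the other pooled regions (adjusted exact p = 0.186, 0.462 and 0.882). Chromosomes I and II did not pass the length test (adjusted exact p = 0.367 and 0.647). In the 373 highest-signal nuclear regions, X held 21.4% (adjusted exact p = 0.0862). Without regions near tRNA starts, an alternative chosen after the data were seen, X held 18.3% (adjusted exact p = 0.669).

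Of 19973 nuclear protein-coding genes, 512 had a reproducible region assigned, with the nearest start within 2000 bp. Among 26 lists of genes fixed before the data were examined, 2 were assigned regions more often than other genes and 1 less often (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment over the lists). Body wall muscle genes had 5 of 38 (13.2%, odds ratio 5.81, adjusted exact p = 0.0329). These included unc-60, an actin-depolymerizing factor, with a summit 306 bp from its start and a signal of 128, unc-112, a kindlin of the muscle attachment, at 474 bp and 125, unc-97, a LIM-domain attachment protein, at 1130 bp and 112.1, and unc-54, the muscle myosin heavy chain, at 96 bp and 102. The unc-60 summit was equally near, at 306 bp, to the start of F53E2.2. Translation factors also had 5, of 41 (12.2%, odds ratio 5.32, adjusted exact p = 0.0329). The leading members were the initiation factor subunits eif-3.E (217 bp, signal 197), eif-3.B (242 bp, signal 172) and eif-3.C (184 bp, signal 127), and iff-2, an eIF5A gene (76 bp, signal 143). Chemoreceptor genes had 9 of 1371 (0.656%, odds ratio 0.238, adjusted exact p = 2.98e-06). Those with the highest signal were sre-23 (626 bp, signal 535), str-56 (1397 bp, signal 493), srd-43 (1199 bp, signal 228.7) and srh-269 (289 bp, signal 140). The regions of all 4 lay closer to small RNA starts, the snoRNA genes ZK265.10 at 67 bp and T06C12.16 at 44 bp and the tRNA genes WBGene00014478 at 9 bp and WBGene00014499 at 23 bp.

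All 3 calls were lost against genes that had a pooled region assigned, where 0 lists passed and each of the 3 had an adjusted exact p of 0.299; 3 lists had an unadjusted p under 0.05 there. The muscle list did not pass without replicate 1 (adjusted exact p = 0.256), and the translation list did not pass without replicate 2 (adjusted exact p = 0.0939). Over 8 alternatives the muscle call was lost in 6, with adjusted exact p from 0.0623 to 0.394, the translation call in 3, and the chemoreceptor call in 1. With any start within 2000 bp, the muscle (adjusted exact p = 0.0627) and translation (0.0752) calls were lost.

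The other lists did not pass the test with the settings fixed in advance. Ribosomal protein genes had 6 of 78 (adjusted exact p = 0.0973), led by rps-24 (signal 207) and rpl-3 (signal 180). That list passed in 4 of 8 alternatives, with starts within 500 bp (odds ratio 5.16, adjusted exact p = 0.0141), with any start within 2000 bp (odds ratio 6.09, adjusted exact p = 1.26e-06), without replicate 1 (adjusted exact p = 0.0223) and without replicate 2 (adjusted exact p = 0.00582). Cell cycle genes had 4 of 49 (adjusted exact p = 0.190), led by cye-1, the cyclin E gene (signal 215), and mcm-10 (signal 140). Collagens had 8 of 156 (adjusted exact p = 0.283), led by col-181 (1293 bp, signal 349) and col-85 (341 bp, signal 310), whose summits lay 4 bp and 13 bp from the starts of the tRNA genes WBGene00014540 and WBGene00014524, and passed without replicate 1 (adjusted exact p = 0.0223) and without replicate 2 (adjusted exact p = 0.00582). Chaperones had 3 of 60 (adjusted exact p = 0.647; dnj-29 and cct-2), core histones 3 of 72 (adjusted exact p = 0.810; his-16 and his-31), and nuclear hormone receptors 3 of 269 (adjusted exact p = 0.633; nhr-255 and nhr-1). With any start within 2000 bp, chaperones (odds ratio 3.60, adjusted exact p = 0.0203), core histones (odds ratio 2.92, adjusted exact p = 0.0412) and the splicing list (odds ratio 4.83, adjusted exact p = 0.0203) passed as higher, and nuclear hormone receptors (odds ratio 0.259, adjusted exact p = 0.0409) as lower. Hypodermis and seam genes had 2 of 41 (dlg-1 and sqt-3), neuronal genes 2 of 47 (daf-19 and unc-64), and ceh homeobox genes 2 of 63 (ceh-43 and ceh-39). A single gene was assigned a region in the pharynx list and in the T-box list (tbx-2 in both), the Wnt list (cam-1), the Notch list (dos-1), the vacuolar ATPase list (vha-13), the respiratory chain list (cox-6A) and the splicing list (rsp-1). Among the genes named in this paragraph, the summits of several others were also nearer to a non-coding start: cye-1 (tRNA gene WBGene00022955, 1 bp), nhr-255 (tRNA gene WBGene00014626, 3 bp), cox-6A (snRNA gene F54D8.7, 30 bp), dos-1 (tRNA gene WBGene00014624, 65 bp), ceh-39 (ncRNA gene T26C11.10, 86 bp), dlg-1 (ncRNA gene C25F6.26, 116 bp), ceh-43 (ncRNA gene C28A5.8, 386 bp) and rps-24 (pseudogene WBGene00020295, 388 bp). Somatic gonad genes had 0 of 22, which allows a share of up to 13.6%, and intestine genes had 0 of 30 (up to 10%). Germline genes had 0 of 36 (up to 8.33%), proteasome genes 0 of 33 (up to 9.09%), hlh genes 0 of 25 (up to 12%), forkhead genes 0 of 15 (up to 20%) and Hox genes 0 of 6 (up to 50%). The reproducible regions nearest to the fkh-6 start, at 2059 bp and 2248 bp, lay just past the 2000 bp limit, so fkh-6 had none assigned.

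The tagged gene itself lay in a dense stretch of regions. The gene fkh-6 (WBGene00001438) is on chromosome II, 4379585 to 4383406, on the minus strand. Within 20 kb of its start there were 8 reproducible regions, against a mean of 0.297 in 1000 random windows, of which 0% were as full (permutation). Their summits ran from 4373134 to 4395966, a span of 22.8 kb. The highest signal, 183, was at 4392628, upstream of mlt-7, and a signal of 161 was at 4376823, upstream of ntl-2. The summit nearest to the fkh-6 start, at 4381347, was 2059 bp from it, inside the gene, with a signal of 110. Counts within 20 kb were 24 in replicate 1 (0.1% of windows as full), 24 in replicate 2 (1.4%) and 22 in the pooled list (3.4%). Around unc-119, the marker gene mutated in the strain, there were 0 reproducible regions, and the pooled list had 16 (17.4% of windows as full), replicate 1 had 16 (4.2%) and replicate 2 had 13 (31.7%).

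**Figure D4:**
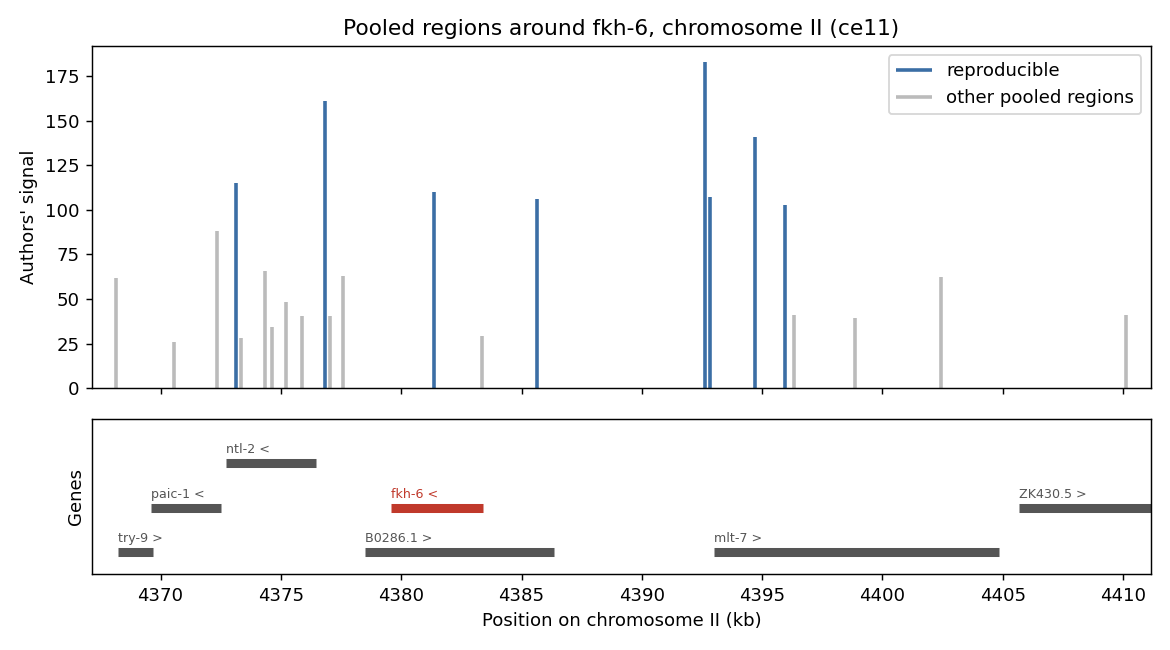
Regions of the pooled list around fkh-6 by summit position on chromosome II (x axis, kb, ce11) and the authors' signal (y axis), with protein-coding genes below and arrowheads for their strand. Of the 8 reproducible regions, that nearest to the fkh-6 start has its summit inside the gene, and the others lie on both sides.

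The same libraries processed on ce10 gave 811 reproducible regions, 44 more than on ce11. The pooled lists held 26152 and 26164 regions, and their signals at the same rank differed by a median of 0.0116%. The lowest signal kept was 87.5 in ce10 and 89.1 in ce11. X held 183 and 180 regions, and chromosome II held 129 and 118.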

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

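The test of mitochondrial coverage was chosen after the result was seen. The 21 mitochondrial regions of the reproducible list were left out of the tests of gene starts, motifs, chromosomes and gene lists, and are a signal outside those tests. They are counted in the recovery and signal agreement of the replicates. They included the highest-signal region, and 17 were among the 100 highest. Regions nearest to the starts of COX3 and ND1 reached signals of 1087 and 581. High copy number of mitochondrial DNA is a candidate explanation, and it needs broad coverage. Pooled regions covered 51.2% of the mitochondrial genome, just over the bound of 50% set for it, with 46.1% in replicate 1 and 53.3% in replicate 2, so the bound was passed in the pooled list and in replicate 2 and not in replicate 1. Regions of the reproducible list itself covered 46.7%, under the bound. The bound was chosen after the result was seen and was passed only narrowly, so it does not decide on copy number. No biological explanation was tested.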

How the results depend on the processing

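Of 98 alternative values, 71 were labelled the same, 14 fell below the threshold, 11 moved and 2 reversed. The same meant an unchanged direction and side of the threshold, a move within the error or, for counts, a change within a set ratio. By that ratio, 540 regions against 767 and 2 or 4 called lists against 3 were the same. The forkhead motif, at 13.8% of summits, reversed from below its flank to above the other pooled regions at equal GC (9.10%) and the dinucleotide shuffles (9.03%), both chosen after seeing the data and both past the threshold. It stayed below the flank without passing the test in the 8 other alternatives, although in the highest-signal quartile, which is not among them, it was at 17.7% of summits and in 13.4% of flanks (exact McNemar p = 0.312), and at 17.5% and 17.1% of regions near protein-coding starts and away from non-coding ones. The shares at gene starts (20.6% to 58.1%) and at tRNA, snoRNA, snRNA and ncRNA starts stayed above the other pooled regions, but against the other regions at a −log10 q-value of 2 or more, those at gene starts (43.2%) and snRNA starts (1.61%) no longer passed (Fisher's exact p = 0.0538 and 0.0745). Recovery in replicates 1 and 2 was 66.6% and 71.2% with summits within 50 bp, 88.5% and 94.3% among 1534 regions of each replicate, and 96.2% and 98.04% in the full lists, which follows from stricter or wider matching. The Spearman correlation of signal between the replicates was 0.615 for reproducible and 0.496 for all matched regions within 50 bp, and 0.422 for all matched regions within 200 bp. X held 21.4% in the higher-signal regions and, chosen after seeing the data, 18.3% without regions near tRNA starts, neither past the threshold. Lists past the threshold numbered 6 with any start within 2000 bp (4 higher and 2 lower, with muscle and translation factors not among them) and 0 among genes with a pooled region; the cause was not tested. Of 3 called lists, chemoreceptors lost the call only against genes with a pooled region. Windows of 10 and 40 kb around fkh-6, the nuclear-only values, the background by q-value and the sets without regions near non-coding starts were also chosen after seeing the data. Unknown depth limits all region counts.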

Other observations

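The tests of GC content, of reproducible regions and signal near fkh-6 and of the B box share, and the subsets by distance to non-coding genes, were chosen only after the results were seen. Small RNA genes dominated the strongest nuclear regions. Of the 50 highest-signal nuclear regions, 39 lay within 500 bp of a tRNA, snoRNA or snRNA start, or 78.0% (95% Wilson interval 64.8 to 87.2), against 14.7% (11.5 to 18.7) of the 373 lowest. Of 612 nuclear tRNA genes, 146 had a reproducible summit within 100 bp, or 23.9%, as had 48 of 346 snoRNA genes, 9 of 129 snRNA genes and 3 of 261 miRNA genes. A B box core, the internal promoter element GGTTCGANNCC, lay within 100 bp of 57.9% of summits near tRNA starts and within 100 bp of the flank point in 2.07%. These summits were chosen for lying near tRNA genes, which hold this element. The contrast therefore does not show what FKH-6-GFP recognises. Among the 434 regions away from non-coding starts, 252 had a protein-coding start within 500 bp, or 58.1%, against 23.6% of other pooled regions. The nuclear regions ranked 20 and 24 in the reproducible list, chosen after their values were seen, had no non-coding start within 500 bp: chromosome I, 933358 to 933680, intergenic and 4965 bp from nas-30, and chromosome III, 3499877 to 3500201, in an intron and 965 bp from M01F1.9.

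For the regions at tRNA genes, GC content alone was argued against: at the summit GC of the reproducible regions, 0.849% of random nuclear positions and 1.39% of the other pooled regions lay within 500 bp of a tRNA start, against 19.4%. The share of summits in coding exons, 3.22%, decides nothing here, since these have 42.4% GC and summits near tRNA genes 50.8%. Reads shared between identical gene copies may add to the pattern. A summit lay within 100 bp of 126 of 469 tRNA genes with an identical copy, or 26.9%, and of 20 of 143 without, or 13.99% (odds ratio 2.26, Fisher's exact test, two-sided, p = 0.00160). Genes without a copy therefore also had regions. Genes with and without a copy may differ in other ways, which were not tested, so the difference does not show that shared reads caused it. Chromatin that is recovered with any antibody stays open, since control libraries were not analysed here, and no biological explanation was tested.

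For the stretch around fkh-6, extra transgene copies of the locus are a candidate explanation that cannot be told apart from binding there. The bound set in advance was at most 2.5% of random windows holding as many pooled regions, and the value, 3.4%, missed it. Its 95% Wilson interval, 2.44 to 4.71, includes the bound, and the use of this interval was decided after the value was seen. On the point value of the pooled list alone the explanation would have been rejected. In the replicates' own lists the values were under the bound, which was set for the pooled list. They were 0.1% (interval 0.0177 to 0.564) in replicate 1 and 1.4% (0.836 to 2.34) in replicate 2. The reproducible regions themselves had 0% of random windows as full, and 1 of the 8 was in a coding exon, against 3.12% elsewhere (Fisher's exact test, two-sided, p = 0.231). The median pooled signal within 20 kb was 62.6 against 35.0 elsewhere, and 0.119% of 839 random windows were as high, so the stretch was raised. The reproducible regions are the highest-signal pooled regions, so this median partly restates their count. Both extra copies and binding would raise the signal there, which keeps the explanation open. For extra copies of the unc-119 rescue gene the bound was also missed, with 17.4% of windows as full (interval 15.2 to 19.9). The values were 4.2% (3.12 to 5.63) in replicate 1, narrowly over the bound, and 31.7% (28.9 to 34.6) in replicate 2. The prediction was not met, but this does not exclude extra copies. The pooled count around fkh-6, which is carried on a transgene, missed the bound too.

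Other hypotheses were tested by single values. The excess on X may come in part from the position of tRNA genes, of which 45.1% are on X. Among regions away from them the odds ratio of X against the other pooled regions was 1.12 (Fisher's exact test, p = 0.320). Within 500 bp of tRNA starts, X held 48.3% of reproducible and 35.4% of other pooled regions (odds ratio 1.70, Fisher's exact test, p = 0.0100). An excess over the other pooled regions therefore remained there. Counted per gene, no excess on X passed the test. A reproducible summit lay within 100 bp of 71 of 276 tRNA genes on X, or 25.7%, and of 75 of 336 on autosomes, or 22.3% (odds ratio 1.21, Fisher's exact test, two-sided, p = 0.342). GAGAGA was not explained by non-coding genes, since away from them it was at 24.7% of summits and in 6.45% of flanks (exact McNemar p = 5.14e-14). Unannotated tRNA-type promoters do not account for most regions away from non-coding genes, where 3 of 434 summits, or 0.691% (95% Wilson interval 0.235 to 2.01), had the B box core, against 57.9% near tRNA starts. Whether a few are such promoters stays open, since with 3 summits and 0 flanks the exact McNemar p, 0.250, is the smallest possible. Gene starts were not shared equally by all pooled regions (odds ratio 2.5), but against the stronger other regions the difference did not pass the test (Fisher's exact p = 0.0538). Base composition of the summit windows taken whole does not account for the forkhead motif. It was at 13.8% of summits, against 9.03% in 200 dinucleotide shuffles and 9.10% of other pooled regions at equal GC. The shuffles do not keep the change of GC within a window, and 27.8% of other pooled summits were in coding exons, against 3.22%. Whether FKH-6 binds these motifs stays open, since GAGAGA and GGGCGG rose in the same way and the stricter form GTAAACA did not.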
